A study of Danio rerio with 13 samples.

How the data were processed

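The samples were 13 microarrays of RNA from whole zebrafish (Danio rerio) embryos at 48 hours after fertilisation, injected at the 1 to 2 cell stage with a morpholino (MO, an antisense oligonucleotide that blocks the translation or splicing of its target transcript). Per the labels, 6 arrays held RNA of embryos injected with an MO against SMN and 7 arrays RNA of embryos injected with an MO against Gemin2, each called a biological replicate. On every array this RNA was labelled with Cy5, and the other channel held Cy3-labelled RNA of embryos injected with a control MO, pooled from 6 independent batches into 1 common control sample. No array had the dyes the other way round. Which step of its target each MO blocks is not given in the sources used here, and neither is whether replicates came from separate clutches, so p-values measure the spread between these RNA samples.

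The deposited values are the authors' log ratios of the 2 channels, 1 per row and array; the scanner intensities were not used here. The scale was taken as log2: the values ran from -7.54 to 8.01, which in base 10 would be ratios beyond the range of a scanner, but a natural logarithm was not excluded. The direction, MO over control, is likely and not certain, and rests on the labels' dyes and on the series design naming the MO first. The background correction, the normalization and any centring are not given in the sources used here. The deposited array medians were 0.0433, 0.0849, 0.0483, 0.0369, 0.0399 and 0.0737 for SMN MO replicates 1 to 6, and 0.0811, 0.122, 0.053, 0.0074, 0.0038, 0.0175 and 0.0129 for Gemin2 MO replicates 1 to 7. The SD of the log2 ratios over rows was between 0.840 and 1.33 per array. With no intensities in hand, signal over background is unknown, and the number of arrays limits the precision.

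Of 23232 rows, 18964 had values on the SMN MO arrays and 19310 on the Gemin2 MO arrays, in each case on all arrays of the group or on none. Values in both groups were present for 18670 rows, which held 18341 distinct profiles; rows repeating a profile on all arrays were counted once. Row names came from the platform's annotation table, in which 11724 rows had 1 gene symbol, 0 had several and 11508 had none. Symbols were updated through the synonyms of the RefSeq gene table of assembly GRCz12tu: 3568 rows had a current symbol, 8022 were updated and 134 matched nothing and kept the old symbol. No coordinates were used. Rows of one symbol were averaged per array, which left 16653 features, 8363 of them named genes; 1397 of these had 2 or more rows. The comparison of a value table with scanner values that would bear out the pairing of rows and symbols could not be made, and checks within the table, given in the report, did not bear it out. Symbols are therefore used as the annotation of a row.

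The fit used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 13 arrays with a mean per group, values as deposited, and at least 4 arrays with values per group. Each group mean was tested against 0, and the SMN MO mean against the Gemin2 MO mean, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A test against 0 leaves out the spread of the control RNA, which was a single pool, and takes in any dye bias. The difference between the groups does neither if a row holds the same oligonucleotide in both groups, which is not established. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. There were 39 lists, of which 38 had at least 5 measured members and were tested. Correlations across rows used permutations in NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 under Python 3.11.15, and plots used matplotlib 3.10.9.

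On simulated data with the spread of the 16653 features and 300 features changed in SMN MO only, limma recovered 4% of 100 features changed by a log2 of 0.5, 55% of 100 changed by 1 and 95% of 100 changed by 2 for SMN MO against control, with 11 false calls. For SMN MO against Gemin2 MO it recovered 1%, 18% and 84% at these sizes, with 9 false calls, and for Gemin2 MO, which was left unchanged, it made 0 false calls. With so few features changed, the adjusted threshold was stricter than in the real fits, where 39.1% to 42.2% of features passed. Errors were also drawn independently for each array. These percentages therefore do not carry over to the real fits. The size of 0.5 was first tried beside 1, dropped because recovery was near 0, and then put back beside 1 and 2. A simulated shift of 0.5 in a list of 48 members among 8363 named genes was called by camera (adjusted p = 1.6e-22), with 0 of the other 37 lists called. The other simulated genes differed only by noise, which makes camera more sensitive than on the real data. Adding 0.5 to the same list on the real SMN MO arrays gave an adjusted p of 0.0286 in camera.

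The groups, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names smn1, gemin2 and every measured neurexin gene; for each comparison the 8 named genes highest and the 8 lowest among those past the threshold, with 1 sign on every array of the group for the tests against control; and per list up to 3 members past the threshold with the largest change, or up to 2 members where none passed. The text gives part of those. The update of symbols, the collapse of repeated spots, the scaling by median absolute deviation in 1 alternative, and the choice of which lists to describe were settled after the data had been seen. The alternatives covered array centring, quantile and scale normalization, averaging of rows, the arrays in the fit, array weights, a robust prior, thresholds, leaving out each array, and replicate number as a block; fits on replicates 1 to 3 or 4 to 6 alone were added later. No columns were left out.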

Results

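The survival motor neuron protein SMN and its partner Gemin2 belong to the complex that assembles the small nuclear ribonucleoproteins of the spliceosome, and loss of SMN underlies spinal muscular atrophy. Transcript levels in whole zebrafish embryos were compared at 48 hours after fertilisation by 2-colour arrays, 6 for embryos injected with an SMN MO and 7 for embryos injected with a Gemin2 MO, each against 1 pool of control MO RNA. Values are log2 ratios, with positive values likely meaning more transcript in the MO embryos. Arrays are named by their labels throughout. For 16653 features with values in both groups, 8363 of them annotated to a gene, 3 comparisons were made: each knockdown against the pool, and one knockdown against the other.

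Within a group the arrays gave similar profiles, and between the groups they gave unrelated ones. Pearson's r across rows was between 0.498 and 0.788 for the 15 pairs of SMN MO arrays and between 0.131 and 0.807 for the 21 pairs of Gemin2 MO arrays, of which the pairs with replicate 7 lay between 0.131 and 0.384. For the 42 pairs of 1 SMN MO and 1 Gemin2 MO array, r was between -0.0165 and 0.0243. Rows annotated to one gene did not give similar ratios either. Over 2109 pairs of such rows, the correlation of the mean log2 ratio was 0.0032 on the SMN MO arrays, where shuffled rows gave -0.0418 to 0.0382 in 95% of 1000 permutations, and over 2166 pairs it was 0.0148 on the Gemin2 MO arrays (shuffled, -0.041 to 0.0382). A simulated true correlation of 0.1 gave 0.0822 and 0.0816. Rows are not independent replicates. Because of these values, a symbol below stands for the row or rows annotated to that gene, and that the transcript of that gene was measured there is not established.

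**Figure D1:**
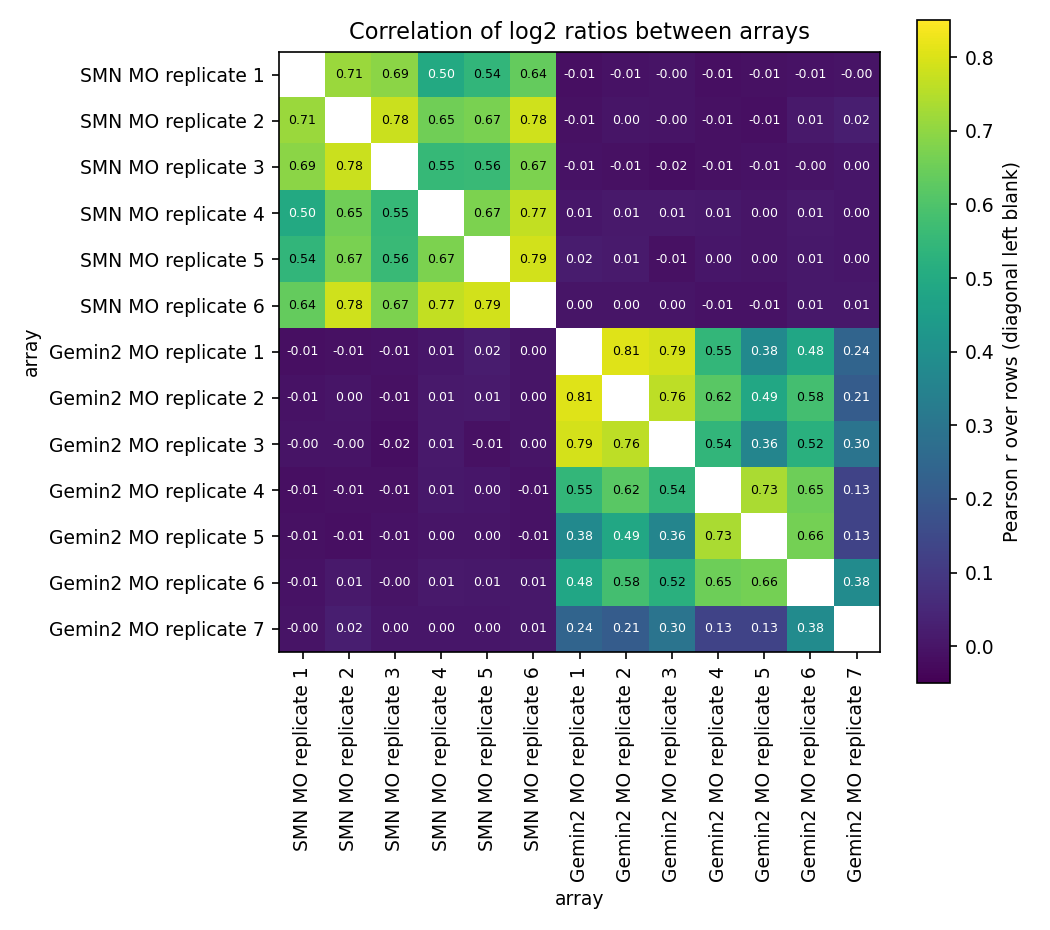
Pearson correlation of log2 ratios across rows for each pair of the 13 arrays, with arrays on both axes and colour and number giving r. Both groups form blocks of positive r, replicate 7 of Gemin2 MO is at 0.131 to 0.384 within its block, and pairs between the groups lie between -0.0165 and 0.0243.

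SMN MO against the control pool asks which transcripts change when SMN is reduced. Rows with a symbol were named here if they passed the threshold with 1 sign on every SMN MO array. The highest of them was annotated to trappc3, a subunit of a vesicle tethering complex, at 3.44 ± 0.67 (SD, n = 6). Next came praf2 at 3.28 ± 1.08, mest at 3.21 ± 0.78, ppid, a cyclophilin, at 3.21 ± 1.09 and nanos1, an RNA-binding protein of the Nanos family, at 3.15 ± 0.66. Among the lowest were rows annotated to slc66a3 at -3.59 ± 1.02, to opn1sw2, the blue cone opsin, at -3.47 ± 1.61, to the homeobox gene pknox1.1 at -3.36 ± 1.74, to pam16, a part of the mitochondrial protein import motor, at -3.23 ± 0.89 and to zeb1b, a zinc finger transcription factor, at -3.04 ± 1.22. All 10 had 1 sign on all 6 arrays by the rule of choice, and their adjusted p-values in limma were between 9.74e-08 for trappc3 and 0.000222 for pknox1.1. In all, 6509 features (39.1%) passed the threshold, 2939 higher and 3570 lower, where an unadjusted p under 0.05 was reached by 7969. The excess of lower calls was absent with the SMN MO arrays fitted alone (4048 higher, 4028 lower). With the likely direction of the ratio the falls were larger, and with the ratio turned the rises would be: 2318 called features were lower by a log2 of at least 1 and 743 higher by as much, and the median called change was -1.24 for lower and 0.807 for higher features. The count leaves out the spread of the control pool and includes dye bias. It also takes the arrays as independent, which the split of the replicates described below puts in doubt.

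The target cannot be checked in the SMN MO embryos, since the 1 row annotated to smn1 had no value in either group. The row annotated to gemin2 was at -0.62 ± 0.44 on the SMN MO arrays (SE 0.22, adjusted p = 0.0323 in limma), below 0 on 6 of 6. With 5 arrays it stayed below 0 but no longer passed without replicate 1 (-0.64, adjusted p = 0.0535), 2 (-0.67, 0.0509), 4 (-0.65, 0.0552), 5 (-0.54, 0.101) or 6 (-0.50, 0.123). It did not pass either when limma's treat was asked for more than a 1.2-fold change (0.166).

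Of 7 measured members of the SMN complex list, 0 rose and 2 fell on the SMN MO arrays, gemin2 and gemin4, the latter at -1.01 ± 0.41 (adjusted p = 0.000643). The 2 rows annotated to gemin4 were both below 0, and the less changed of them was at -0.30 when tested singly (adjusted p = 0.255). Of 10 Sm and LSm genes, which encode the ring proteins of spliceosomal small nuclear ribonucleoproteins, 0 rose and 5 fell, among them lsm4 at -1.43 ± 0.35, snrpb at -1.14 ± 0.46 and snrpd1 at -1.12 ± 0.71. In the spliceosome list 6 of 63 rose and 17 fell, with srsf11 at -2.59 ± 0.72, prpf6 at -2.45 ± 1.12 and bcas2 at -2.29 ± 0.86. Of 5 members of the minor spliceosome list 1 rose and 4 fell, with snrnp25 at -2.37 ± 0.67, zmat5 at -1.47 ± 0.42 and snrnp48 at -1.46 ± 0.49. Among 22 genes of synaptic vesicles and transmitter release 1 rose and 10 fell, including the synuclein sncgb at -2.27 ± 0.98 and the synaptotagmin syt5b at -1.76 ± 0.48. In the motor neuron list 2 of 17 rose and 4 fell. The LIM homeobox gene isl2b fell to -1.87 ± 0.91 and isl1a to -1.84 ± 1.45, while chrna1, an acetylcholine receptor subunit of muscle, rose to 1.09 ± 0.43. Of 37 pan-neuronal genes 6 rose and 9 fell, with the tubulin tubb2b at -2.52 ± 1.08. Of 36 neural progenitor genes 6 rose and 12 fell, with her2 at -2.04 ± 0.78 and id1 at -1.84 ± 0.64. Skeletal muscle genes went both ways, with 17 of 68 higher and 16 lower, among them musk, the receptor kinase of the neuromuscular junction, at -2.10 ± 0.37. Of 19 genes of the p53 response 5 rose and 6 fell. Over all 16653 features 2939 were higher and 3570 lower, so a list of any genes would hold calls of both signs. With replicates 1 to 3 alone, a fit of fewer arrays, the calls on gemin2 (-0.32, adjusted p = 0.276), isl1a (-0.76, adjusted p = 0.127) and snrnp48 (-1.17, adjusted p = 0.0878) were lost.

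As sets, 0 of the 38 lists differed from the other named genes in camera after adjustment, and 2 had an unadjusted p under 0.05, minor spliceosome and synaptic vesicle. The adjusted p of both was 0.672. With an estimated correlation 0 passed, and the smallest adjusted p was 0.82. Adjusted over the list alone, the counts were 0 higher and 2 lower for the SMN complex, 1 and 5 for Sm and LSm genes, 6 and 17 for the spliceosome, 1 and 4 for the minor spliceosome, 1 and 10 for synaptic vesicles, 2 and 5 for motor neurons, 6 and 9 for pan-neuronal genes, 7 and 13 for neural progenitors, 19 and 16 for skeletal muscle and 5 and 6 for the p53 response. Of the synaptic adhesion list 2 genes were measured in both groups. One of them, cadm2a, was at 0.64 ± 0.58 (adjusted p = 0.0289), and it did not pass without SMN MO replicate 1 (0.60, adjusted p = 0.0698), 2 (0.48, 0.126), 3 (0.63, 0.0588) or 6 (0.61, 0.0745), nor with replicates 4 to 6 alone (0.29, adjusted p = 0.436). To set a scale, log2 values of 0.25, 0.5 and 1 were added to real lists on the SMN MO arrays and tested with camera. An added 0.5 in the 48 proteasome genes was called (adjusted p = 0.0286) and 0.25 was not (0.689). For the 17 motor neuron genes an added 1 was called (0.00236) and 0.5 was not (0.584). The lists had means of -0.113 and -0.185 before the addition, so the added values are not the net shifts. Both the lists and the added values go by symbol. If symbols do not belong to the values of their rows, camera would likely call few lists whatever the knockdowns did. In all 3 comparisons, 0 called lists therefore sets no bound on changes of these genes.

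Gemin2 MO against the control pool asks the same of Gemin2. Among rows with a symbol, those near the top on the Gemin2 MO arrays were annotated to the sodium channel gene scn5lab at 3.21 ± 1.40 (SD, n = 7), to the transcription factor gene gata3 at 2.88 ± 1.36, to csrp1a, a LIM domain protein, at 2.80 ± 1.28, to gpx1a, a glutathione peroxidase, at 2.48 ± 1.16 and to the forkhead gene foxc1a at 2.31 ± 1.42. Among the lowest were rows annotated to the p21-activated kinase gene pak5 at -4.25 ± 1.06, to abcb8, a mitochondrial ABC transporter, at -3.52 ± 1.74, to slc35g2a at -3.48 ± 1.26, to the transporter gene slc5a11 at -3.29 ± 1.05 and to cth, cystathionine gamma-lyase, at -3.10 ± 1.14. Each had 1 sign on all 7 arrays, again by the rule of choice, with adjusted p-values in limma between 3.02e-07 for pak5 and 7.46e-05 for foxc1a. In all, 6843 features (41.1%) passed, 3217 higher and 3626 lower, and 8237 had an unadjusted p under 0.05. Among called features 2002 were lower by a log2 of at least 1 and 758 higher by as much, with median called changes of -1.08 and 0.767, so that the falls were larger in the likely direction of the ratio and the rises would be with the ratio turned.

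The row annotated to gemin2 was at 0.79 ± 0.59 on the Gemin2 MO arrays (SE 0.20, adjusted p = 0.00545 in limma), above 0 on 6 of 7, with replicate 4 at -0.13. It did not pass with replicates 4 to 6 alone (0.42, adjusted p = 0.305). In the likely direction this is no fall of the targeted transcript, and with the ratio turned it would be a fall. An MO that blocks translation need not lower its transcript, and the row's identity is not established, so the row checks nothing about the labels. A second row annotated to gemin2 had no value. The 1 measured neurexin row, annotated to nrxn3a, had values on the Gemin2 MO arrays alone, where it was at 0.15 ± 0.36 (SD, n = 7; adjusted p = 0.565 in limma) and above 0 on 5 of 7.

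In the SMN complex list 3 of 7 members rose on the Gemin2 MO arrays and 0 fell: prmt5, the arginine methyltransferase acting on Sm proteins, at 1.36 ± 0.38, gemin2, and gemin5 at 0.48 ± 0.30 (adjusted p = 0.0194). The call on gemin5 was lost without Gemin2 MO replicate 5 (0.39, adjusted p = 0.0659) and, at an unchanged 0.48, in a fit of the Gemin2 MO arrays alone (0.0512) and with treat (0.218). Of 10 Sm and LSm genes 2 rose and 3 fell, with snrpe at 0.82 ± 0.43, lsm1 at -1.94 ± 1.81 and snrpb at -1.02 ± 0.64. In the spliceosome list 9 of 63 rose and 17 fell, with snrnp27 at -1.92 ± 1.15, srsf6a at -1.60 ± 1.55 and prpf4 at -1.56 ± 0.91. Of the 5 minor spliceosome genes 1 rose, pdcd7 at 0.62 ± 0.31 (adjusted p = 0.0049, but 0.0693 with treat), and 0 fell. In the motor neuron list 6 of 17 rose and 5 fell, with mnx2a at -2.62 ± 1.18 and olig2 at -1.27 ± 0.73. Of 22 synaptic vesicle genes 5 rose and 4 fell, with the complexin cplx2 at 1.33 ± 0.54 and sncgb at -1.49 ± 1.26. Of 37 pan-neuronal genes 7 rose and 9 fell, with neurod1 at 1.13 ± 0.54 and the growth cone protein gap43 at -1.69 ± 1.04. Of 36 neural progenitor genes 10 rose and 6 fell, with sox11a at 1.46 ± 0.93 and zic2b at 1.26 ± 0.42. Of 68 skeletal muscle genes 8 rose and 13 fell, with the actin gene acta1b at -2.32 ± 1.32 and actn3a at -2.18 ± 1.23. In the p53 list 3 of 19 rose and 3 fell, with casp8 at -2.38 ± 0.82. Over all 16653 features 3217 were higher and 3626 lower, so calls of both signs would be found in a list of any genes. With replicates 1 to 3 alone the calls on snrpb (-0.51, adjusted p = 0.0843), neurod1 (0.65, 0.0687), cplx2 (0.92, 0.0607), pdcd7 (0.41, 0.183) and gemin5 (0.52, 0.0731) were lost. With replicates 4 to 6 alone those on srsf6a (-0.99, adjusted p = 0.138), olig2 (-0.74, 0.0519), gap43 (-1.49, 0.0536), sncgb (-1.02, 0.0577) and gemin5 (0.57, 0.0989) were lost.

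Camera called 0 of the 38 lists for Gemin2 MO, 1 had an unadjusted p under 0.05 (pigment cell, p = 0.0327, adjusted p = 0.766), and with an estimated correlation the smallest adjusted p was 0.889. Adjusted over the list alone, the counts were 3 higher and 0 lower for the SMN complex, 2 and 4 for Sm and LSm genes, 9 and 17 for the spliceosome, 1 and 0 for the minor spliceosome, 6 and 6 for motor neurons, 7 and 4 for synaptic vesicles, 7 and 9 for pan-neuronal genes, 10 and 6 for neural progenitors, 8 and 13 for skeletal muscle and 3 and 3 for the p53 response.

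**Figure D2:**
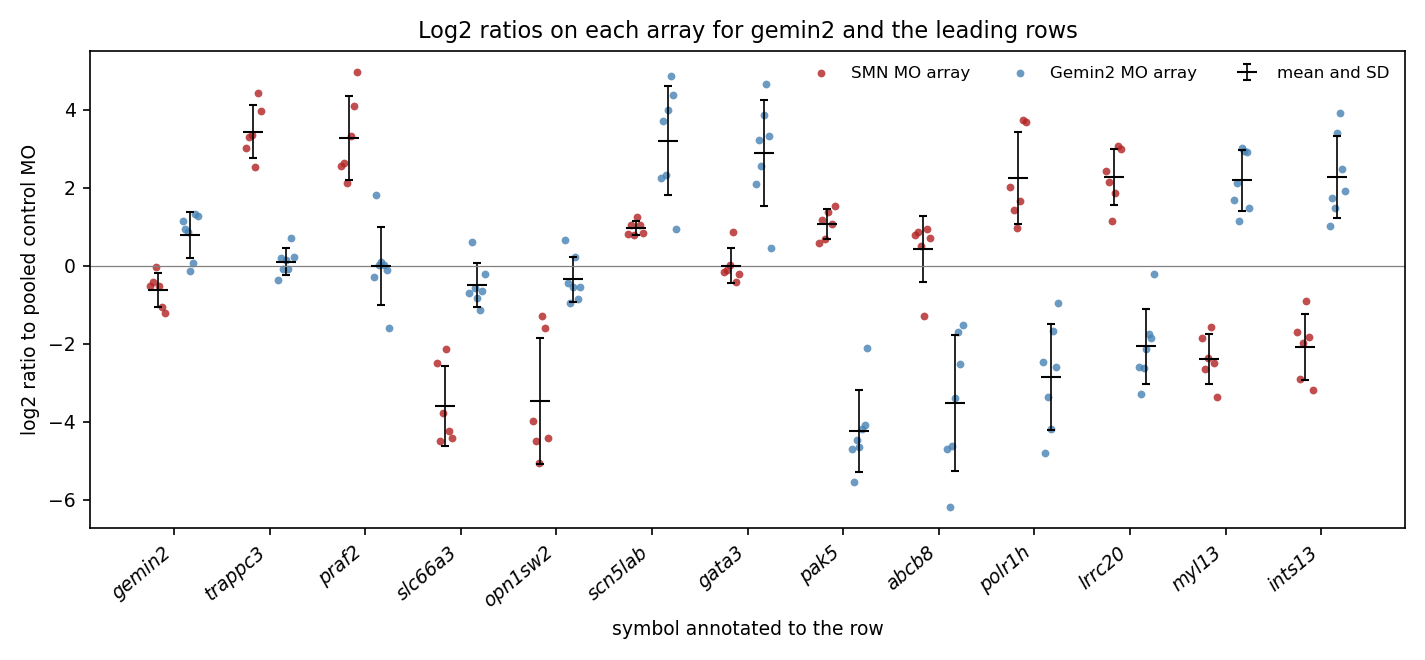
Log2 ratios to the control pool on each array (vertical axis) for gemin2 and the leading rows of the 3 comparisons (horizontal axis, by annotated symbol), with points for single arrays and bars for mean and SD over 6 SMN MO or 7 Gemin2 MO arrays. The pak5 row lies below 0 on all Gemin2 MO arrays, at -4.25 on average, and at 1.07 on average on the SMN MO arrays.

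SMN MO against Gemin2 MO asks where the knockdowns differ. It sets the same row of both groups side by side. The pool and the dyes cancel only if that row holds the same oligonucleotide in both, which is not established. Among rows with a symbol, those higher in SMN MO were led by pak5, with a difference of 5.32 (SE 0.41), polr1h, an RNA polymerase I subunit, at 5.12 (SE 0.60) and lrrc20 at 4.34 (SE 0.43). Those lowest in SMN MO included myl13, a myosin light chain, at -4.58 (SE 0.37), the Integrator subunit gene ints13 at -4.37 (SE 0.47), the replication factor gene mcm10 at -3.90 (SE 0.43) and the kinase gene melk at -3.73 (SE 0.33). For gemin2 the difference was -1.41 (SE 0.30, adjusted p = 0.00124 in limma). In all, 7033 features (42.2%) passed, 3495 higher and 3538 lower in SMN MO (the reverse with the ratio turned), and 8399 had an unadjusted p under 0.05.

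By list, 0 of 7 genes in the SMN complex list were higher in SMN MO and 3 lower, gemin2, gemin4 and the methyltransferase gene prmt5. Of 22 synaptic vesicle genes 2 were higher and 9 lower, and of 5 minor spliceosome genes 0 were higher and 3 lower. Of 36 neural progenitor genes 4 were higher and 15 lower, and of 17 motor neuron genes 4 were higher and 5 lower. Of 68 skeletal muscle genes 18 were higher and 11 lower, with a median difference of -0.00436 and an unadjusted camera p of 0.467. The counts were 2 higher and 3 lower for the 10 Sm and LSm genes, 9 and 14 for the spliceosome, 5 and 10 for pan-neuronal genes and 4 and 5 for the p53 response. Among them snrnp25 differed by -2.87 (SE 0.34), vamp1a by -2.36 (SE 0.38), her2 by -2.11 (SE 0.32) and mnx2a by 3.25 (SE 0.48). Over all 16653 features 3495 were higher and 3538 lower. Camera called 0 of 38 lists, and 2 had an unadjusted p under 0.05, neural progenitor and synaptic vesicle. Their adjusted p-values were 0.484 and 0.536. With an estimated correlation the smallest adjusted p was 0.555. Adjusted over the list alone, the counts were 0 higher and 3 lower for the SMN complex, 3 and 9 for synaptic vesicles, 0 and 3 for the minor spliceosome, 5 and 16 for neural progenitors, 4 and 5 for motor neurons, 18 and 11 for skeletal muscle, 2 and 3 for Sm and LSm genes, 8 and 13 for the spliceosome, 4 and 7 for pan-neuronal genes and 4 and 6 for the p53 response.

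The mean log2 ratios of the knockdowns did not correlate across the 16653 features. Pearson's r was 0.00171 (permutation p = 0.83), Spearman's rho 0.00233 (permutation p = 0.763) and the covariance 0.00114, and 49.9% of features had the same sign in both. A shared control pool alone, simulated with unchanged groups, gave r = 0.518 and a covariance of 0.0758 when the pool varied as the mean of 6 batches, and r = 0.866 and a covariance of 0.455 when it varied as a single sample, so that the observed covariance lay below both. The spread used for the simulated pool was that between arrays, which includes noise of each array that a pool does not share. A pool that varied less would give a smaller covariance, so the gap decides nothing on its own. The pool is 1 sample and cannot be split. Calls in both knockdowns numbered 709 for higher in both, against 568 for independent lists, and 689 for lower in both, against 777. A further 527 were higher in SMN MO and lower in Gemin2 MO (640 if independent) and 684 the reverse (690). The joint fit shares 1 spread per feature, which ties the calls: with the Gemin2 MO rows shuffled 100 times, the count higher in both averaged 648 (602 to 704) and the count lower in both 675 (628 to 712). The observed 709 lay above that range and the observed 689 within it. With each group fitted alone, the counts were 666 higher in both (645 if independent) and 748 lower in both (744).

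**Figure D3:**
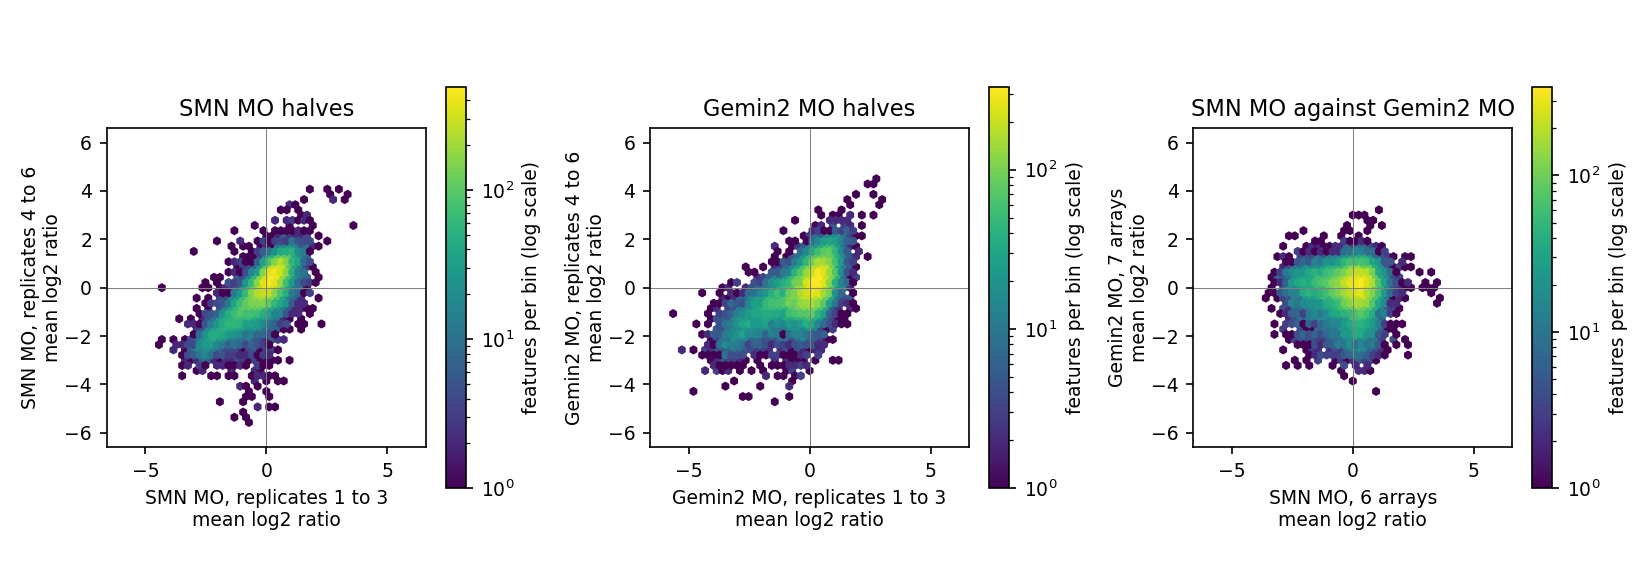
Mean log2 ratio per feature, as counts of features per hexagon on a log colour scale: SMN MO replicates 1 to 3 (horizontal) against 4 to 6 (vertical), the same for Gemin2 MO, and SMN MO against Gemin2 MO. The first panels follow a rising diagonal, and the third has r = 0.00171.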

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

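Of the tests in this part, those of row order, of array noise, of rows of one gene, of repeated profiles and of missing values were chosen after the results they bear on had been seen; the tests of the replicate split and of regrouped arrays were set before.

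The first pattern is that SMN MO and Gemin2 MO ratios do not correlate across rows, although both were read against 1 pool. The pool alone gave a covariance of 0.0758 or more when simulated under assumed spreads of the pool, against 0.00114 observed. The assumed spreads include noise of single arrays, and a pool that varied less would give a smaller covariance. Noise that hides a shared profile is argued against by the mean profiles of replicates 1 to 3 and 4 to 6, which correlated at 0.626 or more within each group. That the knockdowns changed different genes, with rows in register and symbols right, is argued against by rows of one gene, for which the correlation plus its shuffled margin reached at most 0.0544, unless different oligonucleotides of a gene measure different things, which was not tested. A candidate explanation, which stays open, is that the groups do not hold the same oligonucleotide under the same row: the SD over arrays had rho = -0.00219 between the groups but 0.183 and 0.108 within them (at a matched mean ratio -0.00425, 0.108 and 0.0543), though the SD may also follow the response. Against it, missing values agreed by row between the groups (phi = 0.863), with 3628 rows missing in both and 721 if independent. In addition, 172 of 186 spots of the bactin2 oligonucleotides shared 1 profile over the arrays of both groups. For these spots that goes against a mix-up of single rows, but a mix-up of whole oligonucleotides would leave it in place. No constant shift of the row order raised the correlation, which reached 0.0206 over all shifts against 0.0186 to 0.0260 for 100 shuffles. That test says nothing of other mix-ups, and it could show a shift only if the profiles of the groups were alike to begin with. With rows in register but symbols wrong, a true difference between the knockdowns stays open too, since 0.0544 rests on the symbols.

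The second pattern, for which no biological explanation was tested, is that rows annotated to one gene give unrelated ratios. Symbols that do not belong to the values of their rows may account for it, and this stays open: the higher of the correlations for SMN MO and Gemin2 MO was 0.0148, inside the shuffled range. An annotation that names the wrong spots throughout is argued against by repeated spots: all 14 profiles shared by several named rows carried 1 accession each, and 172 of 186 spots of the bactin2 oligonucleotides shared 1 profile, so a mix-up, if any, may lie between oligonucleotides and not between spots. Shared profiles were identical on all 13 arrays, so they bear on how rows were named and are not separate readings. Whether a name belongs to its values they cannot show. Missing values did not follow the gene either (phi at most 0.0256, inside the shuffled range), while they did follow the row, with phi = 0.863 between the groups. They also followed whether a row had a symbol at all, with 11.6% of named and 25.3% of unnamed rows missing for SMN MO and 10.5% and 23.4% for Gemin2 MO, which goes against an annotation wholly unrelated to the table. Among called genes with several rows, all rows had 1 sign for 346 of 495 in SMN MO and 347 of 502 in Gemin2 MO. For the difference it was 363 of 510. The rest were averages of rows of both signs. Calls were made on the averages, which favours rows of 1 sign.

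The third pattern is that the arrays of both groups part into replicates 1 to 3 and 4 to 6. Mean r within minus across these sets was 0.117 for SMN MO and 0.233 for Gemin2 MO, and the split ranked 1 among the 10 possible splits of replicates 1 to 6 in both groups, where the other splits reached at most 0.00213 and 0.0194. Array centring and spread are argued against, since r does not depend on the centre or scale of an array; the split also ranked 1 of 10 after quantile normalization (0.117 and 0.214), a weak test because r hardly moved. A batch of hybridisation, array print or clutch may lie behind it, but 0 batches are named in the labels or the table, so it cannot be told apart from other sources. With replicates 1 to 3 alone the calls were 4766 for SMN MO and 5865 for Gemin2 MO, and with replicates 4 to 6 alone 6107 and 6126. The main fit took the arrays of a group as independent. If arrays of one set share deviations, its p-values may be too small and its counts of calls too high. A fit with these sets as a block was not run, so the size of this effect is unknown. Fits on one set alone cannot show it, since their arrays may share the same deviations.

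Regrouped arrays gave fewer calls than the real grouping for all 3 counts. Arrays of a group correlate with one another, so a lower count after regrouping was likely from the start. A dye bias or a deviation of the pool would pass the tests against control equally, and rows out of register would pass all 3. None of these is excluded. For SMN MO 1 of 32 sign assignments of the arrays, the real one, gave as many calls as 6509, and the highest other gave 1216. For Gemin2 MO it was 1 of 64, with 6843 against 5361 for the highest other. For the difference it was 1 of 100 splits into 6 and 7 arrays, with 7033 against 4030.

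Gemin2 MO replicate 7 stood apart from the other 6 arrays of its group. Its mean r with them was 0.232, where the others had 0.458 to 0.579. Without it the calls for Gemin2 MO were 7433. On this array csrp1a was at 0.0437, with the others at 2.97 to 4.01, and pak5 was at -2.11, with the others at -5.55 to -4.09.

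Single arrays also stood apart for other named rows. The cacng1a row, annotated to a calcium channel subunit of muscle, was at -1 on SMN MO replicate 4 and at -3.28 to -2.63 on the other 5 arrays. On the same array abcb8 was at -1.29, with the others at 0.52 to 0.95, and melk was at -4.27, with the others at -2.84 to -2.29. The snrpb row was at -2.01 on SMN MO replicate 6 and at -1.20 to -0.76 on the others. The lhx1a row, annotated to a LIM homeobox gene, was at -4.56 on Gemin2 MO replicate 6 and at -1.20 to 0.20 on the others. Its group mean of -1.15 (adjusted p = 0.0405 in limma) became -0.58 without that array (adjusted p = 0.144), and the call was also lost, at a mean of about the same size, without replicate 2 (-1.14, adjusted p = 0.0705), 3 (-1.18, 0.0628) or 5 (-1.22, 0.0516). It was lost with treat (0.0978), with the Gemin2 MO arrays alone (0.0738) and with replicates 1 to 3 alone (-0.66, 0.112). In all 8 of 124 groups of values stood apart in this way, where chance gives about 1 in 20.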

How the results depend on the processing

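The fits on replicates 1 to 3 or 4 to 6 alone were chosen after seeing the data. The 3 counts of calls stayed within 1.5 times under centring, quantile and scale normalization, rows tested singly, array weights, a robust prior and a 1.5-fold minimum, and those of SMN MO and Gemin2 MO also in fits of each group alone. The balance for SMN MO, 2939 higher and 3570 lower, became 4048 and 4028 with its arrays alone, 4110 and 4159 with array weights, and 2472 and 3772 with median centring. A threshold of 0.01 gave 4223 calls for SMN MO, 4426 for Gemin2 MO and 4617 for the difference, and treat against 1.2-fold gave 4042 and 4040 for the knockdowns; both are stricter by construction. Leaving out 1 array gave 4976 to 7015, 5748 to 7433 and 6119 to 7557 calls, r between -0.000608 and 0.00414, and 0 lists. Over features called in at least 1 comparison r was -0.0125; the cause was not tested. Fry called 47 lists over the 3 comparisons where camera called 0; fry does not compare a list with other genes, and it had p under 0.05 for 48, 46 and 56 of 100 random lists of 30 genes, against 6, 4 and 4 for camera. With the replicate number as a fixed replicate block the difference had 7221 calls, and as a random block the counts were 6505, 6843 and 7042; deviations of same-numbered arrays correlated between -0.0159 and 0.0152. Both checks need a row to hold the same oligonucleotide in both groups, which is not established, so whether the numbers pair the arrays stays open. Filters on all 13 arrays or on 2 per group were not run, since values were present on all arrays of a group or none. The gene lists were not run on single rows, since lists name genes and not rows. With replicates 1 to 3 alone 95 of the named results kept their call, 11 lost it and 1 changed sign, sulf1 in Gemin2 MO, at -0.12 (adjusted p = 0.689) against 0.89 in the full fit; with replicates 4 to 6 alone 100 kept it and 7 lost it. Among the rows with values under the other settings none changed sign; mdm4 in SMN MO lost its call in the less changed of its rows tested singly (adjusted p = 0.105), and with treat sulf1 in Gemin2 MO (0.0563) and cadm2a in SMN MO (0.153) lost theirs. The call on msi2b in Gemin2 MO was lost without replicate 1 (0.91, adjusted p = 0.0513) or 4 (0.82, 0.0525), against 1.16 in the full fit. Signal over background is unknown here.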

Other observations

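Lists not described in the report also held rows of both signs, where 39.1% of all features were called for SMN MO and 41.1% for Gemin2 MO. On the SMN MO arrays 11 of 53 photoreceptor and retina genes rose and 19 fell, with the cone opsin opn1mw3 at -2.45 (SE 0.31). Of 34 interferon and innate immune genes 4 rose and 8 fell on the SMN MO arrays, with mxc at -2.63 (SE 0.31), and 4 rose and 14 fell on the Gemin2 MO arrays, with tnfa at -1.84 (SE 0.27). The antigen peptide transporter gene tap2a fell in both, to -2.16 (SE 0.36) and -2.17 (SE 0.33), though it was above 0 on 1 of 6 SMN MO arrays. Over all features 689 were lower in both, within the 628 to 712 of shuffled rows, so a list of any genes may hold such a row. Rows named in this section were not checked under the other settings. In the pigment cell list 6 of 29 rose and 7 fell for SMN MO, with tyrosinase, tyr, at -1.17 (SE 0.19), and 1 rose and 9 fell for Gemin2 MO, with foxd3 at -2.08 (SE 0.22). None of these lists passed camera after adjustment, and the identity of the rows is as open as elsewhere.

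The list of genes tied to SMN deficiency in earlier work had 15 measured members. For SMN MO 4 rose and 3 fell, with chodl at 1.68 (SE 0.31) and agrn, which encodes agrin, at 1.34 (SE 0.28). For Gemin2 MO 4 rose and 4 fell, with stmn1a at -1.71 (SE 0.25), coro1ca at -1.38 (SE 0.18) and uba1 at 1.15 (SE 0.22). Camera gave adjusted p-values of 0.912 and 0.981.

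Values were present in 1 group alone for 934 rows. In limma fits of each group alone, 137 of the 294 rows measured only for SMN MO passed the threshold (46.6%), against 48% of its other rows, and 211 of the 640 rows measured only for Gemin2 MO (33%), against 35.4%. In both groups together 3628 rows had no values, where 721 would be so if missing values were independent between the groups.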
